A study of Mus musculus with 8 samples.

How the data were processed

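RNA was sequenced from natural killer (NK) cells of mouse spleen. Per the labels, 4 libraries came from healthy wild-type FVB/n mice (hNK) and 4 from MMTV-PyMT mice (teNK), which the series design calls tumour-bearing. MMTV-PyMT mice carry the polyoma middle T oncogene under a mammary promoter and develop mammary tumours. Per the labels' protocols, the cells were sorted as CD45-positive, CD49b-positive and CD3-negative, and were cultured in medium with cytokines for 12 to 16 h before RNA extraction. Libraries were made with a stranded poly(A) kit, per the labels' protocols. The strain background of the MMTV-PyMT mice, the number of animals behind each library and the cytokines were not given in the sources used here. Nothing in the labels says that the replicates came from separate animals, so the p-values measure only the spread between these libraries, which may be technical.

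The authors deposited 1 file per library with whole-number read counts per Ensembl gene and no normalization. HISAT2 2.1.0, SAMtools, HTSeq and the genome build GRCm38 are named per the submitters' processing notes, with no order or settings. The strand setting of the counting and the annotation release were not given in the sources used here. Each deposited file of counts held 54838 gene identifiers and 5 summary lines, which stayed out of library sizes and tests. Of all reads in the files, 32.3% to 41.2% per library were on the line for reads in no gene and 1.52% to 2.07% on the line for ambiguous reads. The other 3 summary lines, reads with several alignments among them, held 0 in every library, so how such reads were treated cannot be seen. GENCODE M21, an annotation of GRCm38, gave symbols and coordinates for 54809 identifiers, and 29 had no match. Coordinates are positions in GRCm38.

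Reads on genes were 11395122, 12419324, 5800098 and 5202131 in hNK replicates 1 to 4 and 16013680, 16209895, 13111043 and 13837301 in teNK replicates 1 to 4. A floor of 3 counts per library corresponded to 0.238 to 0.542 CPM (counts scaled to library size) in hNK and 0.190 to 0.241 CPM in teNK. Intervals and floors cover counting error only. The descriptions of the teNK libraries say that one library was run in several lanes, and those of the hNK libraries do not, so sequencing layout and group cannot be told apart. No 2 libraries held identical values. Over the 12 pairs within groups, a chi-square comparison of genes with at least 20 reads gave 3.55 to 11.5 per degree of freedom, so no pair agreed within sampling noise and all 8 libraries were counted.

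Counts were analysed in R 4.3.3. In edgeR 4.0.16, genes were kept with filterByExpr by group (13903 of the 27313 with a read), scaled with TMM and tested with the quasi-likelihood F test on the group term alone. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of F. CPM values were computed from the counts with the TMM factors, and means and SDs are over 4 libraries. Where a group had no read, the fold was computed against the mean floor of 3 counts per library. Where a group had 1 to 12 reads in all, the ratio of pooled reads was given with an exact 95% Clopper-Pearson interval, conditional on the total.

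A total of 39 gene lists was fixed before the data were examined, as were the design, the alternatives planned and the rule for genes named. Lists with at least 3 tested members (37) were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Camera compares the members of a list with all other genes. The test was repeated with the correlation estimated for each list. That version takes its degrees of freedom from the libraries, not from the genes, and so has far fewer. A call lost there therefore need not reflect correlation alone. For the type I interferon list the estimate was 0.021, near the preset, and the call was lost too (camera adjusted p = 0.135). Fry, which tests whether the members move one way on balance and makes no comparison with other genes, was run beside camera. The rule for named genes took the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 2, libraries that did not overlap between groups and no predicted-gene name. It added up to 4 members per list with the smallest adjusted p (or the 2 highest expressed where none passed), the sort genes and Xist, and 11 NK cell and DNA methylation genes regardless of their values. Members of lists that were not called could be given as counts.

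The scripts were tested on simulated counts with the means and depths of these libraries, for teNK against hNK over 13903 genes. Of 50 genes changed at each size, 20% were recovered at 1.25-fold, 58% at 1.5-fold, 90% at 2-fold and 100% at 4-fold. There were 9 false calls among 143. The share of genes changed was far smaller than the 51.9% called in the real libraries, so these rates need not hold there. A simulated 1.5-fold shift of the type I interferon list was called as 1 list of 37, and 0 lists were called with no shift. Simulated genes varied independently, whereas the correlation estimated in the real libraries reached 0.57 for the ribosomal protein list. The simulation therefore cannot show how often correlated lists are called falsely.

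Alternatives were RLE and upper-quartile scaling, no filter and a filter of 1 CPM in 4 libraries, the replicate number as a block, each library left out in turn, DESeq2 1.42.0, limma-voom with quality weights, limma-trend, an adjusted p under 0.01, a test against 1.5-fold, a prior count of 0.5, an estimated correlation and fry. Thinning all libraries to the depth of the shallowest, and leaving out the 2 shallowest libraries, were added after the data were seen. Exons of 35 of the 113 named genes overlap those of another annotated gene, 31 of them on the opposite strand. Because the strand setting is unknown, reads there could not be attributed with certainty.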

Results

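Poly(A) RNA of sorted splenic NK cells was sequenced in 8 libraries, 4 from healthy FVB/n mice (hNK) and 4 from tumour-bearing MMTV-PyMT mice (teNK). The design asks how NK cells of tumour-bearing mice differ in gene expression from those of healthy donors. Reads on genes ranged from 5202131 to 12419324 in hNK and from 13111043 to 16209895 in teNK, so hNK values carry the larger counting error. The first principal component held 77.0% of the variance of log2 CPM and separated the groups. Pearson correlations of log2 CPM across genes, which are not independent replicates, were at least 0.982 within hNK and 0.992 within teNK, and 0.929 to 0.940 between groups. The biological coefficient of variation was 10.3% in hNK and 6.52% in teNK.

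In teNK, most tested genes of mature NK cells, activating receptors, cytotoxic effectors, the immediate early response, the interferon responses and the cell cycle rose. Camera with a preset correlation called these lists higher, and with an estimated correlation it called none of them (adjusted p = 0.135 to 0.368). The estimated version also has far fewer degrees of freedom, so correlation between genes need not be the whole reason. *Klrg1*, an inhibitory receptor of mature NK cells, rose 15.1-fold, *Prf1* (perforin) 4.54-fold and the activating receptor gene *Ncr1* 4.83-fold. *Asns* (asparagine synthetase) fell 126-fold, and 52 of 56 cytosolic ribosomal protein genes fell, with a median log2 fold change of -0.55. Markers of platelets and B cells, which are not NK cells, were also higher in the same teNK libraries. Of 13903 genes tested, 3665 rose and 3557 fell in teNK (edgeR quasi-likelihood test, adjusted p under 0.05), and 6681 were not called. Changes of at least 2-fold were called for 1151 higher and 806 lower genes. The libraries of the groups did not overlap in 46.5% of genes, where chance gives 2.86% for 4 against 4. When tested against a change of 1.5-fold, genes higher in teNK numbered 1297 and genes lower in teNK 850.

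**Figure D1:**
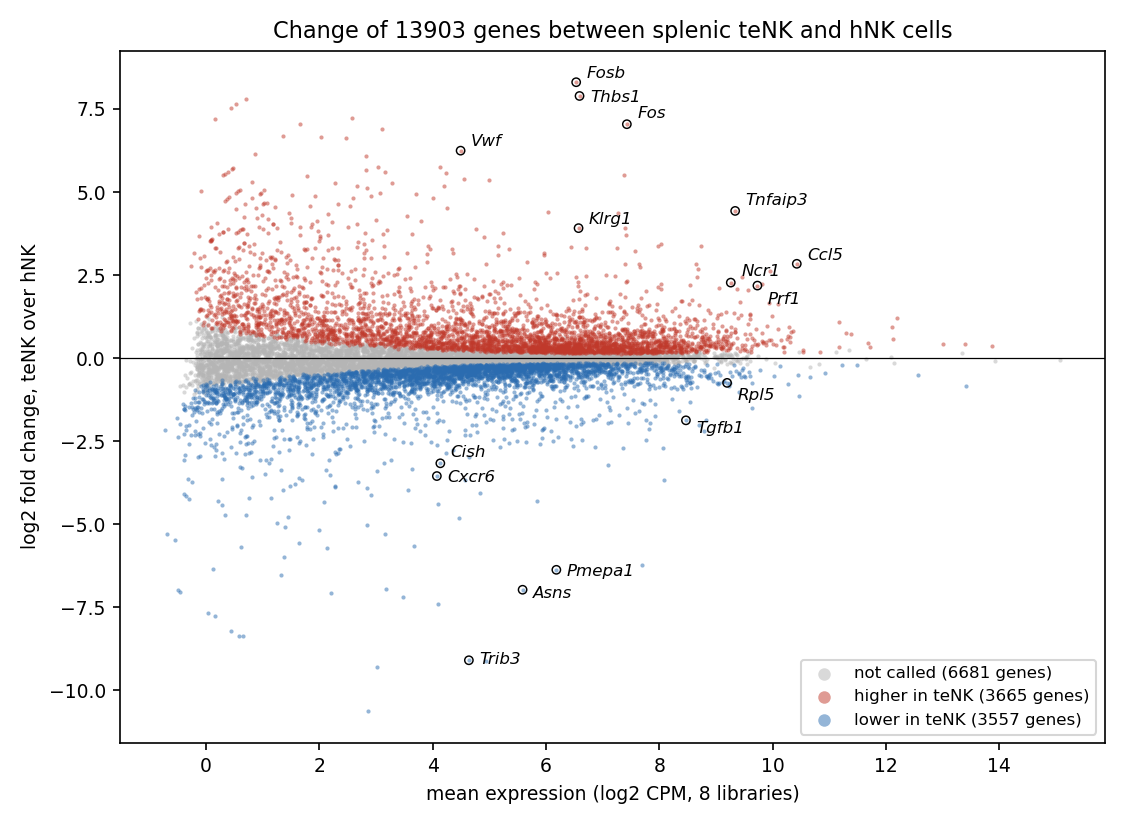
Log2 fold change of teNK over hNK (vertical axis) against mean expression in log2 CPM over 8 libraries (horizontal axis), 1 point per tested gene. The 3665 genes higher in teNK are red, the 3557 lower genes blue and the 6681 genes not called grey; circled genes are among those described in the text, from *Fosb* at 8.31 to *Trib3* at -9.10.

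The 10 largest rises included *Fosb* and *Fos*, transcription factors of the immediate early response, and genes of platelets and B cells. *Fosb* (ENSMUSG00000003545, chromosome 7, 19302696 to 19310051) rose from 0.542 ± 0.126 to 178 ± 29.9 CPM (SD, n = 4), a log2 fold change of 8.31 ± 0.19 (SE) with an adjusted p of 7.23e-15. *Fos* (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273) rose from a mean of 2.18 to 335 ± 4.27 CPM, a log2 fold change of 7.04 ± 0.15. The other 8 genes of this set included *Thbs1* (thrombospondin 1), *Vwf* (von Willebrand factor), *Slc6a4* (the serotonin transporter) and *Mpig6b*, which platelets and megakaryocytes express, and *Cr2*, a complement receptor of B cells. *Thbs1* (ENSMUSG00000040152, chromosome 2, 118111876 to 118127133) rose from 0.712 ± 0.307 to 186 ± 39.1 CPM and *Vwf* from 0.458 ± 0.251 to 40.4 ± 9.66 CPM. Some of these genes were nearly absent from hNK, so their ratios are uncertain. *Plxna4* had 2 reads in all hNK libraries and 562 in teNK, a ratio of 180 (95% interval 49.7 to 1492). *Mpig6b* had 2 and 375 reads (120, 33.1 to 997), *Slc6a4* 3 and 519 (111, 37.8 to 540), *Cr2* 4 and 828 (133, 51.7 to 488) and *Gas2l1* 6 and 672 (71.8, 32.8 to 196). The fitted log2 fold change moved from 6.91 to 7.58 for *Cr2* without hNK replicate 3, from 6.64 to 7.28 for *Mpig6b* without hNK replicate 4 and from 6.07 to 6.95 for *Gas2l1* without hNK replicate 2, and all hNK reads of *Slc6a4* were in hNK replicate 1. *Tmtc1* rose from 0.565 ± 0.246 to 30.6 ± 3.17 CPM, 54.4-fold.

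The largest falls included enzymes and transporters of amino acids. *Asns* (ENSMUSG00000029752, chromosome 6, 7675169 to 7693254) fell from 102 ± 19.5 to 0.791 ± 0.162 CPM (SD, n = 4), a log2 fold change of -6.97 ± 0.18 (SE, adjusted p = 2.88e-14). *Trib3*, a pseudokinase induced by amino acid shortage, had 1954 reads in hNK and 5 in teNK, a ratio of 609 (95% interval 261 to 1879). The amino acid transporter genes *Slc1a4* and *Slc6a9* were 177 (101 to 344) and 126 (66.0 to 277) times more abundant in hNK. *Chac1*, a glutathione-degrading enzyme of the same stress response, had 17.5 ± 3.97 CPM in hNK and no read in teNK, at least 81.7-fold lower at a floor of 3 counts per library. *Nqo1*, a quinone reductase of the oxidative stress response, was 156 (81.6 to 341) times more abundant in hNK, and *Ahrr*, the aryl hydrocarbon receptor repressor, 149 (57.5 to 548) times. *Pmepa1*, a target of TGF-beta signalling, fell from 148 ± 20.6 to 1.79 ± 0.174 CPM, a log2 fold change of -6.37 ± 0.13. *Ppp2r2c* had 2437 and 6 reads (633, 291 to 1727) and *Scn3b* 692 reads and 1 read (1079, 193 to 42679).

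Of 17 tested mature NK genes, 16 rose in teNK, with a median 4.24-fold change (camera adjusted p = 2.33e-10; adjusted p = 0.207 with an estimated correlation). Adjusted over the list alone, 16 rose and 1 fell. *Klrg1* (ENSMUSG00000030114, chromosome 6, 122270596 to 122282882) rose from 11.5 ± 1.33 to 173 CPM (SD 10.01, n = 4), a log2 fold change of 3.91 ± 0.09 (SE, adjusted p = 4.93e-15). *S1pr5*, a receptor for egress of NK cells from lymphoid tissue, rose 9.25-fold, and *Zeb2*, a transcription factor of terminal maturation, 4.24-fold. In the less mature NK list, 6 of 18 genes rose and 11 fell, the same counts adjusted over the list alone, and the list was not called (adjusted p = 0.265). *Ltb* (lymphotoxin beta) fell from 150 ± 21.99 to 36.9 ± 4.91 CPM.

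Of 16 NK identity genes, 11 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.00624; adjusted p = 0.368 with an estimated correlation). *Ncr1* (ENSMUSG00000062524, chromosome 7, 4337724 to 4345164), which encodes NKp46, rose from 209 ± 35.9 to 1013 ± 65.0 CPM, a log2 fold change of 2.27 ± 0.10. *Tbx21* (T-bet) rose 4.19-fold, whereas *Eomes*, the related T-box factor, fell from 786 ± 38.2 to 639 ± 29.2 CPM, a log2 fold change of -0.30 ± 0.07 (adjusted p = 0.00107). Activating receptors and their adaptors rose in 17 of 22 genes and fell in 1 (18 and 1 adjusted over the list alone; camera adjusted p = 1.31e-07; adjusted p = 0.163 with an estimated correlation). *Itgb2*, the shared chain of beta-2 integrins, rose 4.71-fold, *Slamf7* 4.09-fold and *Cd226* (DNAM-1) 2.81-fold. In the Ly49 receptor family, 10 of 11 genes rose (11 adjusted over the list alone; camera adjusted p = 2.95e-05; adjusted p = 0.262 with an estimated correlation), including *Klra8* at 3.56-fold and *Klra4* at 3.10-fold. These genes are near copies of each other and differ between strains, and the strain of the MMTV-PyMT mice is not given, so the assignment of reads to members and the comparison between groups are uncertain.

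Cytotoxic effector genes rose in 14 of 18 and fell in 2 (14 and 3 adjusted over the list alone; camera adjusted p = 0.000225; adjusted p = 0.309 with an estimated correlation). *Prf1* (ENSMUSG00000037202, chromosome 10, 61297833 to 61304680) rose from 306 ± 40.6 to 1389 ± 58.6 CPM, a log2 fold change of 2.18 ± 0.09 (adjusted p = 6.19e-12), and the serpin gene *Serpinb6b* 7.16-fold. *Tnfsf10*, the death ligand TRAIL, fell from 83.4 ± 20.1 to 20.5 ± 1.19 CPM. *Gzmb* (granzyme B) measured 554 ± 148 CPM in hNK and 452 ± 20.5 CPM in teNK, a log2 fold change of -0.29 ± 0.13 that did not pass (adjusted p = 0.0726). *Gzmb* was called lower in 5 of 18 alternatives, with adjusted p from 0.000508 to 0.842 over all 18. Without hNK replicate 1 its log2 fold change was -0.42 with an adjusted p of 0.00196. In the list of cytokines and chemokines, 9 of 19 genes rose and 7 fell, the same counts adjusted over the list alone, and the list was not called (adjusted p = 0.409). *Ifng* (interferon gamma) rose from 20.2 ± 4.62 to 121 ± 7.70 CPM, *Ccl3* 10.3-fold, *Ccl4* 10.9-fold and *Ccl5* 7.16-fold.

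**Figure D2:**
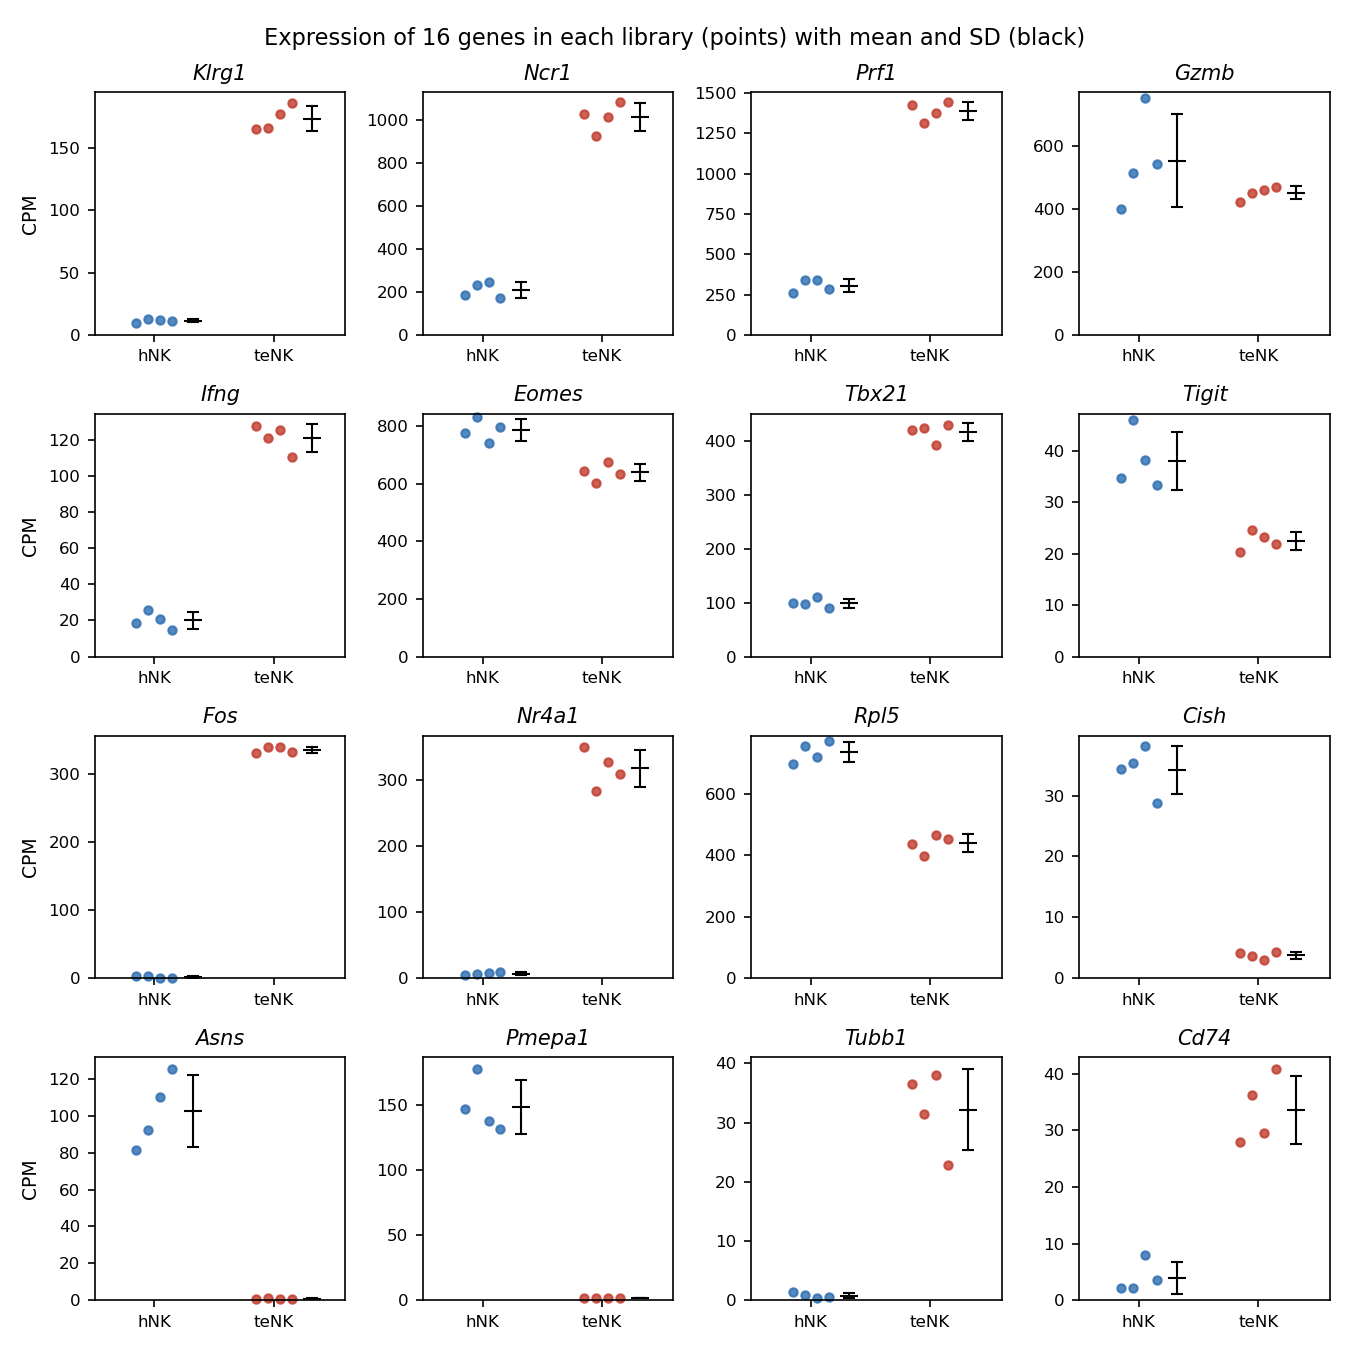
CPM of 16 genes in each library (points), with the mean and SD of the 4 hNK (blue) and 4 teNK (red) libraries in black; every vertical axis is linear and starts at 0. *Klrg1* lies at 11.5 CPM on average in hNK and 173 in teNK, while the *Gzmb* values of the groups overlap.

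Among inhibitory receptors and checkpoints, 7 of 17 genes rose and 6 fell, the same counts adjusted over the list alone, and the list was not called (adjusted p = 0.409). *Lair1* rose 5.17-fold, *Cd160* 3.81-fold and *Lag3* from 0.726 ± 0.376 to 2.31 ± 0.702 CPM. *Tigit* fell from 38.0 ± 5.66 to 22.5 ± 1.79 CPM and *Nt5e* (CD73) from 139 ± 9.82 to 51.1 ± 5.95 CPM. Of 21 chemokine receptor and homing genes, 10 rose and 10 fell, the same counts adjusted over the list alone, and the list was not called (adjusted p = 0.728). *Cmklr1* rose 8.53-fold and the integrin gene *Itga4* 6.16-fold, and *Cxcr6*, a receptor of tissue-resident lymphocytes, fell from 33.8 ± 4.96 to 2.86 ± 0.444 CPM. In the list of ILC1 (a related innate lymphocyte) and tissue residency, 7 of 21 genes rose and 11 fell, the same counts adjusted over the list alone. *Rora* fell from 205 ± 11.1 to 73.4 ± 6.10 CPM and *Ldlrad4* from 62.6 ± 14.0 to 14.8 ± 0.919 CPM, and *Rgs2* rose 3.84-fold. That list was not called (adjusted p = 0.0672) but was called lower in 8 of 18 alternatives, with adjusted p from 7.40e-05 to 0.394 over all of them. The adjusted p was 0.0348 without hNK replicate 1, and 0.0293, 0.0297 and 0.0346 without teNK replicates 1, 2 and 3.

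Immediate early genes, which are transcribed within minutes of a stimulus, rose in 31 of 37 and fell in 4, also when adjusted over the list alone (camera adjusted p = 3.02e-11; adjusted p = 0.207 with an estimated correlation). *Nr4a1* (ENSMUSG00000023034, chromosome 15, 101254269 to 101274795), a nuclear receptor induced by receptor signalling, rose from 7.36 ± 1.74 to 318 ± 28.0 CPM. *Tnfaip3*, a brake on NF-kappa-B signalling, rose 21.6-fold. Transcription factors of lymphocyte dysfunction rose in 13 of 17 and fell in 3, also when adjusted over the list alone (camera adjusted p = 0.00111; adjusted p = 0.207 with an estimated correlation). The largest rises of its named members were those of *Nr4a1*, *Nr4a2* (20.7-fold) and *Nr4a3* (10.1-fold), which also stand in the immediate early list, and *Prdm1* (Blimp-1) rose 2.62-fold. In the list of IL-2, IL-15 and IL-12 cytokine response, 19 of 37 genes rose and 12 fell (19 and 13 adjusted over the list alone; adjusted p = 0.406). Its median log2 fold change was 0.19 and its mean -0.02. *Irf8* rose 5.48-fold, while *Cish*, a feedback inhibitor of IL-15 signalling, fell from 34.1 ± 3.93 to 3.79 ± 0.575 CPM and *Socs1* from 87.8 ± 3.99 to 26.4 ± 2.14 CPM. *Cdkn1a* (p21) fell from 38.3 ± 1.38 to 5.62 ± 0.687 CPM. Of 23 TGF-beta response genes, 7 rose and 12 fell, the same counts adjusted over the list alone, and the list was not called (adjusted p = 0.110). *Tgfb1* fell from 559 ± 73.5 to 153 ± 8.02 CPM and the repressor gene *Ski* from 489 ± 54.8 to 164 ± 7.91 CPM, and *Smad3* rose 2.70-fold.

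Type I interferon response genes rose in 25 of 33 and fell in 2, also when adjusted over the list alone (camera adjusted p = 9.38e-07; adjusted p = 0.135 with an estimated correlation). *Irf7*, a transcription factor that amplifies the response, rose 3.71-fold, *Zbp1*, a sensor of nucleic acids, 3.49-fold and *Samd9l* 2.51-fold. Of 30 genes of interferon gamma response and MHC class I, 20 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.00632; adjusted p = 0.283 with an estimated correlation). *H2-Q7* rose 2.41-fold and *H2-Q6* 2.11-fold, with the reservation that these class I genes are near copies that share reads and vary between strains, and that the strain of the MMTV-PyMT mice is not given.

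Cell cycle genes rose in 43 of 54, and the other 11 were not called, also when adjusted over the list alone (camera adjusted p = 1.66e-08; adjusted p = 0.368 with an estimated correlation). *Cenpf* rose from 6.62 ± 1.89 to 28.2 ± 3.05 CPM, and *Prc1*, a gene of the spindle midzone, 3.64-fold. Histone genes rose in 14 of 24 and fell in 4, also when adjusted over the list alone (camera adjusted p = 0.00624; adjusted p = 0.368 with an estimated correlation). *Hist1h1b* rose 2.82-fold and *Hist1h2ab* 4.04-fold; replication-dependent histone messages lack poly(A) tails and have near copies, so their counts are uncertain. Of 19 genes of DNA methylation, 7 rose and 1 fell (6 and 1 adjusted over the list alone), and the list was not called (adjusted p = 0.152). *Dnmt1*, the maintenance methyltransferase, rose from 230 ± 13.8 to 354 ± 7.74 CPM, a log2 fold change of 0.62 ± 0.06 (adjusted p = 3.32e-07), and *Dnmt3a* rose by 0.39 ± 0.07. *Dnmt3b* did not pass (-0.16 ± 0.12, adjusted p = 0.261). *Tet1*, which oxidises methylcytosine, rose 2.76-fold.

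Cytosolic ribosomal protein genes fell in 52 of 56, also when adjusted over the list alone, and their median log2 fold change was -0.55 (camera adjusted p = 2.64e-13; adjusted p = 0.366 with an estimated correlation). *Rpl12* (ENSMUSG00000038900, chromosome 2, 32961559 to 32965345) fell from 525 ± 34.7 to 286 ± 20.4 CPM and *Rpl5* from 736 ± 33.5 to 439 ± 28.8 CPM. In the same libraries *Rn7sk*, a small nuclear RNA without a poly(A) tail that was chosen after its values were seen, took 1.29% to 1.77% of reads in hNK and 0.640% to 0.822% in teNK. Among called genes, 44 snoRNA genes were lower and 7 higher. Of 66 oxidative phosphorylation genes, 26 fell and 3 rose (25 and 3 adjusted over the list alone), with a median log2 fold change of -0.18 (camera adjusted p = 0.00109; adjusted p = 0.556 with an estimated correlation). *Uqcrq*, a subunit of complex III, fell from 38.4 ± 5.15 to 22.8 ± 1.01 CPM, and *Cycs* (cytochrome c) rose 1.72-fold. Glycolysis and hypoxia genes were split, with 11 of 34 higher and 10 lower (11 and 12 adjusted over the list alone; adjusted p = 0.788). Cholesterol synthesis genes fell in 10 of 29 and rose in 6, the same counts adjusted over the list alone, and the list was not called (adjusted p = 0.0859), except lower without hNK replicate 1 (adjusted p = 0.0237), without a filter (0.0373) and by fry (0.00562), over a range up to 0.527. In the list of heat shock and unfolded protein response, 11 of 26 genes rose and 12 fell, the same counts adjusted over the list alone (adjusted p = 0.409). The named members of that list all fell, namely *Chac1*, *Trib3*, *Asns* and the stress factor *Ddit3*, from 62.3 ± 7.70 to 21.9 ± 0.882 CPM, and its median of -0.10 was unchanged with *Chac1* at its bound. Of 21 p53 targets, 9 rose and 7 fell, the same counts adjusted over the list alone (adjusted p = 0.728), and fry gave the direction lower where the median of 0.12 was above 0.

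**Figure D3:**
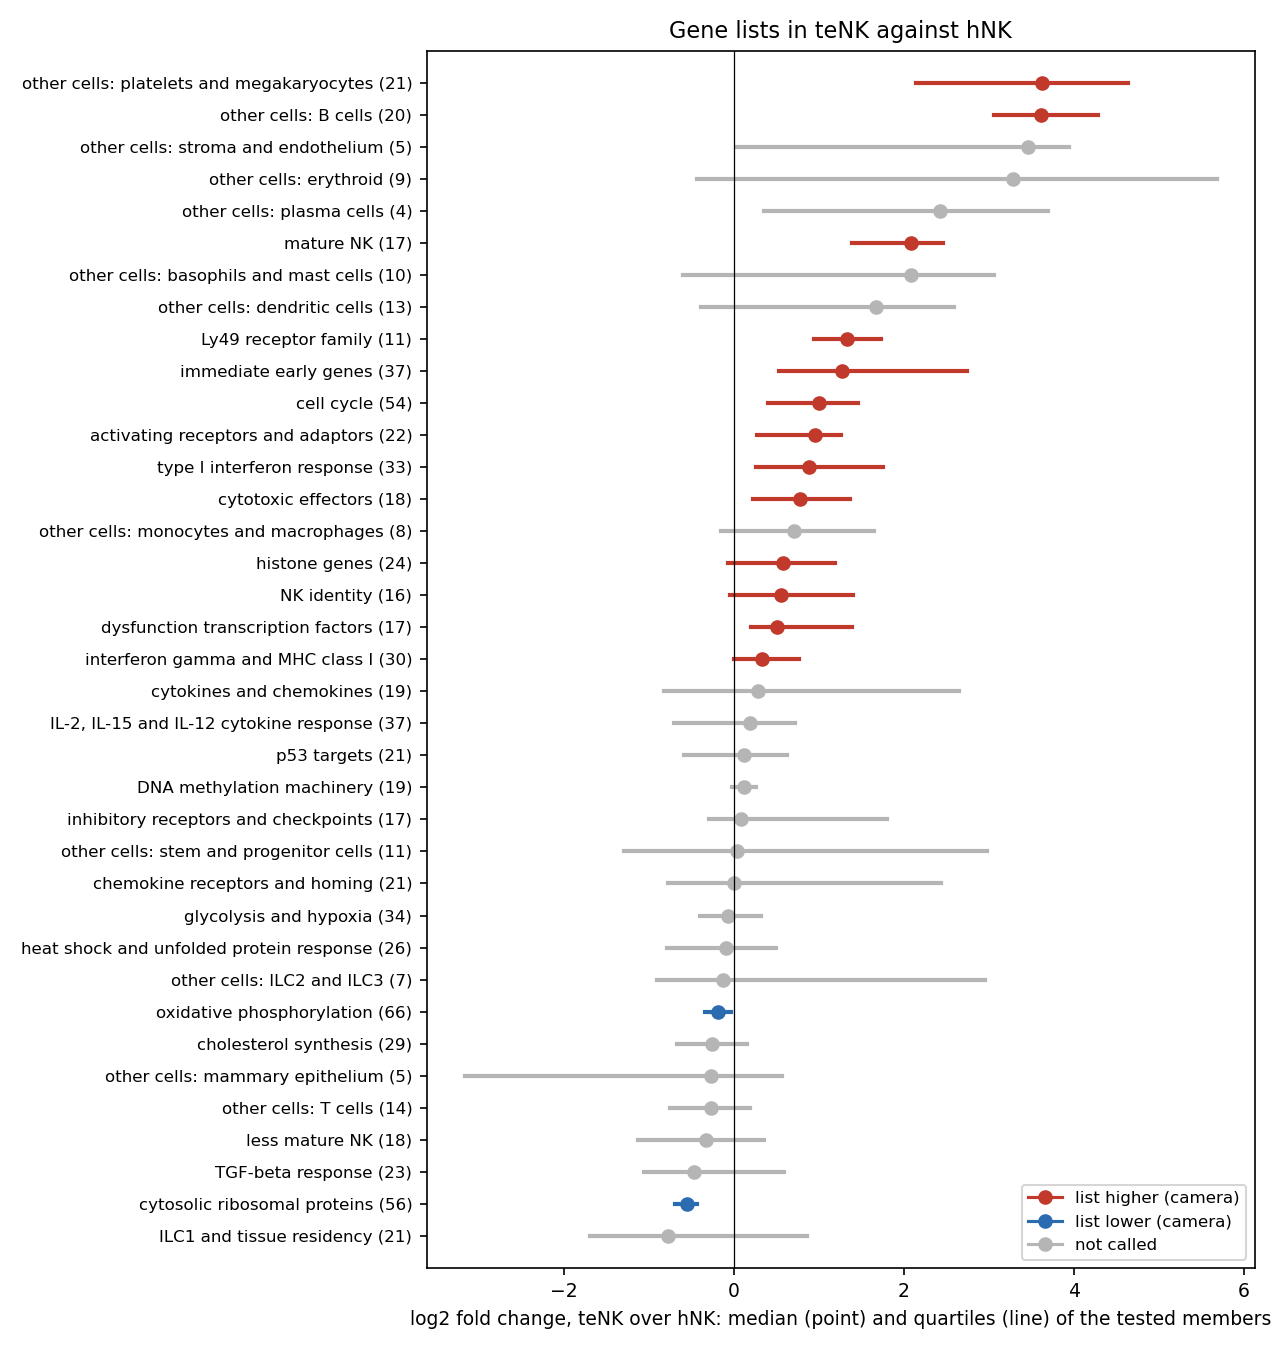
Median (point) and quartiles (line) of the log2 fold change, teNK over hNK, of the tested members of 37 gene lists, with the number of members in brackets; red and blue lists were called higher and lower with a preset correlation, a call that all 15 lose with an estimated correlation, and grey lists were not called. The platelet and B cell lists have medians of 3.63 and 3.61, and the ribosomal protein list has a median of -0.55.

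Markers of other cells were measured in the same libraries. Of 21 platelet and megakaryocyte genes, 20 rose in teNK, also when adjusted over the list alone, with a median 12.4-fold change (camera adjusted p = 3.95e-10; adjusted p = 0.207 with an estimated correlation). *Tubb1*, the platelet tubulin, rose from 0.770 ± 0.469 to 32.2 ± 6.90 CPM and *F5* (coagulation factor V) from 1.04 ± 0.294 to 41.9 ± 11.6 CPM. Of 20 B cell genes, 19 rose, also when adjusted over the list alone, with a median 12.2-fold change (camera adjusted p = 1.94e-07; adjusted p = 0.322 with an estimated correlation). *Cd74* rose from 3.92 ± 2.76 to 33.6 ± 6.02 CPM (hNK mean 2.59 without hNK replicate 3), and *Cd22* and *Ms4a1* (CD20) reached 9.87 ± 1.59 and 8.02 ± 2.16 CPM in teNK. *Tubb1* and *Cd74* were higher in each of the 4 teNK libraries than in any hNK library, as were *Klrg1*, *Ncr1*, *Prf1*, *Ifng*, *Fos* and *Nr4a1*. The lists of plasma cells (3 of 4 higher, 1 lower), monocytes and macrophages (5 of 8 higher, 2 lower), basophils and mast cells (6 of 10 higher, 3 lower) and dendritic cells (8 of 13 higher, 3 lower; 9 and 3 adjusted over the list alone) were not called, with adjusted p of 0.111, 0.272, 0.124 and 0.110. The dendritic cell list was called higher when thinned to one depth (0.00945), without the 2 shallowest libraries (0.0413) and by fry, over a range of 0.000505 to 0.400. The list of basophils and mast cells was called higher without the 2 shallowest libraries (0.0361), without a filter (0.00352) and by fry, over 7.87e-05 to 0.759, and that of monocytes and macrophages without a filter (0.0239) and by fry, over 0.00987 to 0.443. Erythroid genes (5 of 9 higher, 2 lower; 6 and 2 adjusted over the list alone) and those of stroma and endothelium (3 of 5 higher) were not called either (adjusted p = 0.0825 and 0.0667). The erythroid median was 3.28 and became 2.50 with *Car1*, which had no read in 1 group, at its bound. Without hNK replicate 1, 2, 3 or 4 the erythroid list was called higher (adjusted p = 0.0327, 0.0108, 0.00493 and 0.00638), as it was without teNK replicate 1 or 3 (0.0282 and 0.0298), over a range of 3.07e-06 to 0.734. With all libraries thinned to one depth, the medians of the members still tested were -0.50 for the erythroid list and -0.13 for basophils and mast cells (2.08 at full depth). Those of the other lists were 0.06 for stroma (3.46 at full depth), 1.17 for plasma cells (2.42), 2.04 for dendritic cells (1.67) and -0.81 for stem and progenitor cells (0.04). The medians at full depth and at one depth need not cover the same members, so they do not show whether any member changed with depth. The stroma list kept fewer than 3 tested members at one depth and was not tested there. The stroma list was called higher without hNK replicate 1 or 2 or teNK replicate 2 (0.0342, 0.0286 and 0.0373, range 0.000296 to 0.283), and the plasma cell list without hNK replicate 2 (0.0371, range 0.000296 to 0.401).

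Genes of T cells (3 of 14 higher, 5 lower), ILC2 and ILC3 (3 of 7 higher, 2 lower), stem and progenitor cells (4 of 11 higher, 5 lower) and mammary epithelium (2 of 5 higher, 3 lower) were not called as lists, with adjusted p of 0.242, 0.586, 0.940 and 0.409. Adjusted over the list alone, these counts and those above with no second count were the same. The ILC2 and ILC3 list had a median of -0.13, a mean of 0.84 and the test direction higher. No neutrophil gene and 1 of 5 sex-linked genes was abundant enough to test. The sort genes *Ptprc* (CD45) and *Itga2* (CD49b) were expressed at 3567 ± 132 and 422 ± 16.3 CPM in hNK and rose by a log2 fold change of 0.58 ± 0.08 and 0.58 ± 0.06 (SE). *Cd3d* rose from 2.25 ± 0.930 to 4.91 ± 0.527 CPM. *Cd3e* measured 2.18 ± 1.46 CPM in hNK and 1.43 ± 0.540 in teNK, and *Cd3g* 20.2 ± 8.46 and 23.01 ± 2.95, and neither passed (adjusted p = 0.287 and 0.283). *Cd3g* was called higher without hNK replicate 4 (adjusted p = 0.00174) and without the 2 shallowest libraries (0.000939), and the range over 18 alternatives was up to 0.642. *Xist*, the X inactivation RNA of females, had 819 ± 63.6 CPM in hNK and 1195 ± 171 in teNK, and 4 Y-linked genes had 1 read in the 8 libraries together.

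With the preset correlation, camera called 13 lists higher and 2 lower. With an estimated correlation camera called 0 of the 37, with 7 at an unadjusted p under 0.05, while fry called 34. The gene lists lower in teNK numbered 4 without hNK replicate 1. Exons of *Ifng*, *Irf7*, *Ddit3*, *Rpl5*, *Rpl12*, *Prc1*, *Itga4*, *Eomes*, *Xist*, *Zeb2* and *Ldlrad4*, among others, overlap those of another gene with reads. The origin of part of their reads is therefore uncertain.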

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

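The test of handling on the immediate early genes was written after its result was seen, and thinning to one depth was added after the data were seen. In 240 groups of 4 libraries, 12 single libraries stood apart from the other 3 of their group, where chance gives 12 at 1 in 20. *Thbs1* was at 127 CPM in teNK replicate 4 (others 199 to 210), *Nr4a3* at 132 CPM in teNK replicate 2 (158 to 162) and *Cdkn1a* at 6.65 CPM in teNK replicate 1 (5.22 to 5.33). *F5* was at 1.48 CPM in hNK replicate 3 (0.873 to 0.915), *Lair1* at 12.2 CPM (6.73 to 7.38) and *Klra8* at 14.7 CPM (11.3 to 11.7) in the same library. *Cmklr1* was at 17.5 CPM in hNK replicate 2 (9.58 to 10.9), *Cenpf* at 3.81 CPM in that library (7.15 to 7.77) and *Ccl5* at 229.6 CPM in hNK replicate 4 (367 to 378). Near the floor, *Slc6a4* was at 0.249 CPM in hNK replicate 1, *Ppp2r2c* at 0.241 CPM in teNK replicate 3 (0.0635 to 0.0764) and *Scn3b* at 0.0635 CPM in teNK replicate 2, with no read of *Slc6a4* or *Scn3b* in the others of the group.

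In 8 marker lists, the members too low to test had a higher summed expression in each teNK library than in any hNK library. Their summed expression averaged 2.90 CPM in teNK and 0.482 in hNK for B cells, 3.48 and 2.01 for plasma cells, 3.07 and 1.46 for monocytes and macrophages, and 4.64 (3.04 without teNK replicate 1) and 0.216 for neutrophils. It averaged 3.13 and 1.14 CPM for basophils and mast cells, 7.19 and 0.843 for erythroid cells and 1.47 and 0.792 for mammary epithelium. For mammary epithelium the groups barely separated, at 1.049 CPM in the lowest teNK library and 1.047 in the highest hNK library. The gap was also slight for plasma cells, at 2.67 and 2.59 CPM. The single untested platelet gene averaged 0.152 CPM in teNK and had no read in hNK. The groups overlapped for dendritic cells, stem and progenitor cells, and stroma. They overlapped too for T cells, at 0.499 CPM in teNK and 0.848 in hNK (0.170 without hNK replicate 4), and for ILC2 and ILC3, at 0.637 and 0.929 (0.597 without hNK replicate 4).

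Platelet and B cell markers rose in teNK. Lower depth of hNK was argued against for the 29 members called higher at full depth and still tested at one depth. Their median log2 fold change was 3.44 at one depth, against 3.74 at full depth. Called members too low to test at one depth are not covered. Over all members tested at each depth, called or not, the medians were 3.63 and then 3.52 for platelets, and 3.61 and then 3.09 for B cells. RNA carried over from these cells may contribute, which was tested on further genes listed after the main results were seen. Outside the fixed platelet and B cell lists, 31 of 33 platelet genes were called higher and 1 lower, and 23 of 30 B cell genes higher and 3 lower. Their median log2 fold changes were 1.15 and 1.34. Camera gave an adjusted p of 3.32e-13 and 8.31e-07, and of 0.0105 and 0.0657 with an estimated correlation, so that the B cell call is lost. These counts include genes that hNK expressed, such as *Tln1* (952 CPM) and *Syk* (166 CPM), which cannot tell carry-over from expression by NK cells. Of the listed genes under 5 CPM in hNK, 13 of 13 (100%) and 15 of 17 (88.2%) were called higher, against 26.0% of all 3862 tested genes under 5 CPM in hNK. Among abundant genes chosen after their values were seen, *Ppbp* rose 5.86-fold (18.3 ± 6.57 to 106 ± 24.1 CPM) and *Pf4* 4.43-fold (5.07 ± 2.30 to 21.7 ± 6.39), less than the platelet list's median of 12.4-fold, *Itga2b* rose from 3.78 ± 1.48 to 34.0 ± 5.91 CPM, *Igkc* from 1.40 ± 1.54 (0.768 without hNK replicate 3) to 19.6 ± 4.79 and *Cd79a* from 0.310 ± 0.468 (0.0831 without it) to 2.37 ± 0.795, while *Ighm* measured 95.8 ± 17.8 CPM in hNK and 96.5 ± 6.99 in teNK (log2 fold change 0.02, adjusted p = 0.901). Platelets themselves carry CD49b, the CD49b gate would remove most B cells, 6 platelet members and 1 B cell member had at least 5 CPM in hNK, 2 and 4 stand in other lists, and a change in expression by NK cells or in the spleen of tumour-bearing mice was not tested.

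Cytosolic ribosomal protein genes fell in teNK. They lay -0.64 (log2) from genes matched on exon length, GC content and expression, with a median absolute deviation, scaled to an SD, of 0.37. The exon length joined the exons of all annotated transcripts (4043 bases for *Rpl18*), and GC content was that of the longest transcript. The match therefore cannot decide whether the length or GC content of the transcripts present contributes. Reads lost to processed pseudogenes were argued against, since the median of 106 annotated ribosomal pseudogenes was -0.59. Scaling moved the median little, to -0.55 under the scaling nearest to 0. A lower expression of these genes in NK cells of tumour-bearing mice remains a hypothesis, and the sequencing layout, which follows the group, and a difference in library composition, with *Rn7sk* at 1.29% to 1.77% of reads in hNK and 0.640% to 0.822% in teNK, stay open and untested.

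Immediate early genes rose in teNK. Lower depth of hNK was argued against, since the median log2 fold change at one depth was 1.33 over 36 members, against 1.40 for the same members at full depth. Different handling or culture of the groups cannot be told apart from an effect of the tumour, because both follow the group: the lowest teNK library lay 1.64 (mean log2 CPM of the list) above the highest hNK library. The cells were cultured with cytokines for 12 to 16 h before RNA extraction, and these genes respond to handling within minutes to hours.

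Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many called genes as the real split, which was the real one itself. For the genes, edgeR called 7222 in the real split and 0 as the highest of the others, where the highest count at an unadjusted p under 0.05 was 1207. Every other split mixes the groups, so the group difference widens the spread within its sides and lowers its calls. Chance is therefore not excluded by this count. For the gene lists, 6 of the 35 splits gave as many calls, the real one included, so chance was not excluded by their number, with 15 lists in the real split and 16 as the highest of the others. The other 5 put 3 libraries of one group with 1 of the other and so keep part of the real difference, while the 18 splits with 2 libraries of each group on both sides gave 0 to 8 lists by camera.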

How the results depend on the processing

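Thinning to the shallowest library and leaving out the 2 shallowest libraries were chosen after seeing the data. Over 18 alternatives other than the test against 1.5-fold and the adjusted p under 0.01, 2979 to 4151 genes higher in teNK and 2825 to 3949 genes lower in teNK were called, and 78.0% to 98.7% of the calls were kept. Tested against 1.5-fold, genes higher in teNK numbered 1297 and genes lower in teNK 850, a stricter question by construction. With the replicate number as a block the counts were 3581 and 3401, and the numbers were not shown to pair libraries, since 3 of 8 correlated best with their own number. Without each library in turn, 3380 to 3766 genes were higher and 3203 to 3497 lower, and 13 to 16 gene lists higher in teNK and 2 to 4 gene lists lower in teNK were called, 4 of them without hNK replicate 1. With no filter on low counts, 4 lists were lower, with more genes tested. With an estimated inter-gene correlation, camera called 0 lists higher and 0 lower, with 7 at an unadjusted p under 0.05, whereas fry called 25 and 9. The cause of the change without hNK replicate 1 was not tested. Of 2032 recomputed values of 113 named genes, 2025 kept their direction and side of the threshold and 7 were newly called (*Gzmb* 5, *Cd3g* 2). Of 665 list values, 604 were the same, 46 were newly called (19 under fry) and 15 were lost, all with the estimated correlation. The 2 hNK libraries with the fewest reads limit the genes expressed at a few reads.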

Other observations

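The tests below were written before their results were seen, on gene lists written after the genes with the largest falls had been seen. Targets of ATF4, the transcription factor of the amino acid response, fell in teNK beyond the genes named in the results. Of 36 tested targets outside those genes, 36 (100%) were called lower, with a median log2 fold change of -1.78 and quartiles of -2.57 and -1.32 (camera adjusted p = 2.05e-21 over 5 lists; adjusted p = 0.0434 with an estimated correlation). The median was unchanged with *Aldh1l2*, which had no read in teNK and was at least 18.1-fold lower, at its bound. They included enzymes of serine synthesis, *Phgdh* (73.0 ± 11.1 CPM in hNK and 12.4 ± 1.04 in teNK, n = 4) and *Psat1* (116 ± 31.2 and 25.2 ± 2.65), and *Shmt2* of one-carbon metabolism (173 ± 14.7 and 31.1 ± 1.93). The transfer RNA synthetase genes among these targets fell as well, with *Aars* at 289 ± 10.6 CPM in hNK and 44.3 ± 2.91 in teNK.

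Targets of NRF2, the transcription factor of the oxidative stress response, were called lower in 18 of 23 (78.3%) and higher in 2, *Trim16* and *Abcc4*, with a median of -0.90 (camera adjusted p = 1.14e-07; adjusted p = 0.0434 with an estimated correlation). *Txnrd1* (thioredoxin reductase) measured 370 ± 47.3 CPM in hNK and 84.8 ± 5.75 in teNK, *Gclm*, of glutathione synthesis, 91.0 ± 8.24 and 23.1 ± 1.91, and *Ftl1* (ferritin light chain) 370 ± 71.7 and 67.6 ± 4.54. Of aryl hydrocarbon receptor targets, 2 of the 3 tested (66.7%) were called lower, *Tiparp* among them at 187 ± 20.5 and 52.3 ± 2.33 CPM, which is too few to decide (camera adjusted p = 0.129; adjusted p = 0.176 with an estimated correlation). A lower activity of ATF4 and NRF2 in teNK is a candidate explanation for the falls of *Asns*, *Trib3*, *Chac1* and *Nqo1*, as a hypothesis from the same libraries. Differences in culture between the groups would act on these genes too and cannot be told apart from an effect of the tumour, because they would follow the group.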
